A study of Homo sapiens with 6 samples.

How the data were processed

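Poly(A) transcriptomes of 3 human non-small cell lung cancer lines, A549, HCC827 and H1975, were compared after 48 h with AL-X or with its solvent DMSO. AL-X is the code name of 9α,11α-dihydroxy-kaurenoic acid, given at 10 µg/mL. Each line gave 1 DMSO and 1 AL-X library, 6 libraries in all. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an mRNA kit (SureSelect XT HS2) and size-selected on beads. The submitters' processing notes name bcl2fastq 2.20 and the GRCh38 build. The aligner, the counter, the annotation release, the strand setting and any use of molecular barcodes are not given in the sources used here.

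The authors deposited whole-number read counts per Ensembl gene, not normalized, in a single table of 60671 gene rows and 6 columns. Library totals ranged from 98139178 to 126840915 counts. Of the gene identifiers, 60401 matched a table of gene symbols, and 58453 had coordinates in GENCODE release 29 on GRCh38, used for position, gene type and length. Exonic length is that of all annotated exons of a gene merged, not of a single transcript. The authors' own release is not known, so positions are those of release 29. Because the strand setting is not given, counts of overlapping and antisense genes cannot be told apart. The same holds for reads shared by near-identical copies, among them HSPA1A with HSPA1B, FRG2B with FRG2, RFPL4A with its paralogs, HSPE1-MOB4 with HSPE1, and mitochondrial genes with their nuclear copies.

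Libraries were paired by cell line, as the cell line tag in the labels gives it, so the line entered the model as a block. The across-line effect of AL-X was tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr on the treatment groups, quasi-likelihood test with robust shrinkage) and Benjamini-Hochberg adjustment at 0.05. This kept 20344 genes, 17587 of them with a symbol, and left 2 residual degrees of freedom. The 3 lines are the replicates of a shared effect. Nothing says that a library stands for more than 1 culture, and the edgeR p-values measure only the spread between these lines. A standard error (SE) was obtained from the fold and its quasi-likelihood F value.

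Within a line there is no replicate, and no test was made. The log2 fold of TMM-scaled counts per 1e6 counts (CPM) with a prior count of 2 was used, and a gene was counted as differing at 2-fold or more with at least 5 CPM in the higher library. Exact binomial 95% intervals of the count ratio cover counting error only, since reads are not shown to be independent molecules. Where a library held 0 counts, a lower bound of the fold was computed against a floor of 3 counts in that library, or against the mean of the 3 libraries' floors where a whole group was at 0. Overlaps between lines were set against the number given by independent lists. Whether 1 line differed from the mean of the other 2 was tested by an interaction term in edgeR, with 1 residual degree of freedom, on the assumption that the lone line varies like the others.

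Before the data were examined, 30 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and, beside it, with the correlation estimated per list. Within each line the median fold of a list was placed among 10000 random lists of the same size, matched on mean expression over 50 bins. For the tests of explanations, bootstrap 95% intervals over the members of a list were drawn 2000 times. Members are not independent replicates. The rule named up to 12 genes higher and 12 lower with the largest across-line fold among those at adjusted p under 0.05, with the same sign in 3 lines and a mean of at least 5 CPM. It added per line up to 4 genes higher and 4 lower with at least 10 CPM in the higher library, up to 2 members from either end of each list, and 25 genes fixed in advance. Genes without a symbol were left out of it except for the 25. Some genes are not reported here. NFIB, STEAP2, SPTB, SESN2, PLK3, HSPA6, SLC7A11, AKR1C1, SOCS3, SGK1, CXCL8, KLF4, JUN, FOSL1, KRT16P1 and ENSG00000285991 were chosen after their values were seen.

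The alternatives were DESeq2 size factors, library totals as the only scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, no robust shrinkage, no block, and each line left out. Leaving mitochondrial genes out before scaling, and testing lists for line differences, were added after seeing the data. With 2 pairs left, 1 residual degree of freedom remained.

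The scripts were tested on simulated counts drawn from the real means and dispersions. The changed genes averaged at least 5 CPM and, in the across-line simulation, had the same fold in every line. For the across-line test on 19127 genes, 35.8% of genes changed by 2 log2 units were recovered, as were 100% of those changed by 4 and 100% of those changed by 6. This recovery does not cover genes whose fold differs between lines or genes of lower expression. There were 14 false calls in that simulation and 0 calls in one without changed genes. For the test of A549 against the other lines on 18802 genes, 17.9%, 97.0% and 95.5% of genes were recovered at 4, 8 and 12 log2 units, with 9 false calls. A simulated list shifted by 2 log2 units was called by camera with the preset correlation and missed with the estimated one (adjusted p = 0.203), and 0 of 29 unshifted lists were called with the preset one. The simulated genes were drawn independently, so the 0 of 29 does not cover lists whose members vary together. The binomial interval held the true ratio in 96.1% of simulated genes.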

Results

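RNA was measured in 3 lung cancer cell lines treated for 48 h with the diterpenoid AL-X at 10 µg/mL or with DMSO. All are lung adenocarcinoma lines, and HCC827 and H1975 carry mutant EGFR. Every line gave 1 library per treatment. Total counts were 110445983 and 121552821 for A549 with DMSO and AL-X, 126840915 and 98139178 for HCC827, and 104648304 and 112133896 for H1975. The number of genes with at least 1 count was lower with AL-X in each line, at 24046 against 26979 in A549, 26694 against 27874 in HCC827 and 24278 against 27163 in H1975. The first principal component held 45.1% of the variance and the second 26.7%.

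The across-line comparison asks which genes responded to AL-X in the same way in all 3 lines. All 13 mitochondrially encoded mRNAs, which specify core subunits of the respiratory chain and ATP synthase, fell, with a median log2 fold of -10.02 in A549, -5.91 in HCC827 and -8.22 in H1975. Genes of the mitochondrial genome took 6.87% of all counts in A549 with DMSO (exact binomial 95% interval 6.87 to 6.88) and 0.0201% with AL-X (0.0198 to 0.0203). In HCC827 the share was 6.69% (6.69 to 6.70) and then 0.656% (0.654 to 0.658), and in H1975 6.41% (6.40 to 6.41) and then 0.0535% (0.0531 to 0.0539). MT-ND3 (ENSG00000198840, mitochondrial genome 10059 to 10404), a subunit of complex I, changed by -8.92 log2 units (SE 0.95, edgeR adjusted p = 0.0105), and MT-CO3 (ENSG00000198938, 9207 to 9990), a subunit of cytochrome c oxidase, by -9.46 (SE 1.41, adjusted p = 0.0225). MT-CO1 (-9.18, SE 1.49), MT-CYB (-8.42, SE 1.21), MT-ATP6 (-8.39, SE 1.16) and MT-CO2 (-8.04, SE 1.24) fell too.

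Among mitochondrial tRNA genes, MT-TQ had 3185, 637 and 159 counts in A549, HCC827 and H1975 with DMSO and 0 counts in each with AL-X. It was at least 587-fold, 180-fold and 42.8-fold lower by line, and at least 323-fold lower for the group mean. MT-TY was at 0 counts with AL-X in A549 and H1975, at least 1078-fold and 1094-fold lower there, and MT-TS1 was at least 815-fold and 1085-fold lower. MT-TC was at least 421-fold lower in A549 and 479-fold lower in H1975. These tRNA genes lie on the minus strand. Because the strand setting is not given, their counts cannot be told apart from transcripts of the other strand, and may not stand for mature tRNAs. Nuclear copies on chromosome 1, MTCO1P12 (log2 fold -8.76, SE 0.98) and MTATP6P1 (-8.31, SE 1.02), fell with the genes whose reads they can share. The mitochondrial ribosomal RNAs did not pass the test. MT-RNR1 differed by -3.80, 0.16 and -2.88 log2 units in A549, HCC827 and H1975 (adjusted p = 0.272) and MT-RNR2 by -5.35, -1.74 and -4.14 (adjusted p = 0.166).

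**Figure D1:**
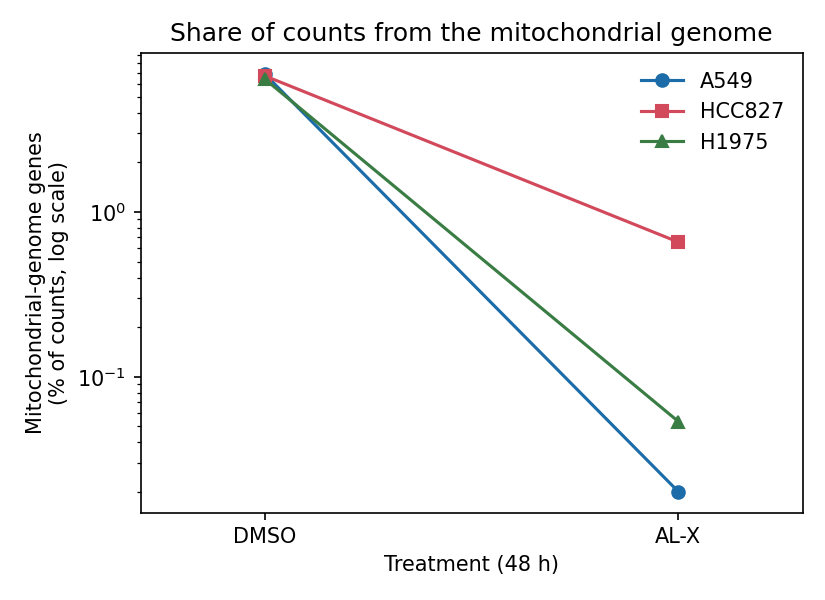
Share of all counts taken by genes of the mitochondrial genome (%, log scale) in the DMSO and AL-X libraries of each line, 1 library per point. The share fell from between 6.41% and 6.87% to 0.0201% in A549, 0.0535% in H1975 and 0.656% in HCC827.

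Nuclear genes that rose in all 3 lines included stress-response transcription factors and signalling genes. DDIT3 (ENSG00000175197, GRCh38 chromosome 12, 57516588 to 57521737), which encodes the stress factor CHOP, rose by 5.18 log2 units (SE 0.78, edgeR adjusted p = 0.0237), with 7.04 in A549, 5.03 in HCC827 and 3.52 in H1975. ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), a related transcription factor, rose by 4.91 (SE 0.81, adjusted p = 0.0327). CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373), a secreted matricellular protein, rose by 6.43 (SE 0.92, adjusted p = 0.0184), and HBEGF (ENSG00000113070, chromosome 5, 140332843 to 140346631), an EGFR ligand, by 6.00 (SE 1.08, adjusted p = 0.0477). The co-stimulatory ligand TNFSF9 (4.73, SE 0.79), the homeobox gene MSX1 (4.58, SE 0.75), the long non-coding RNA MIR22HG (4.32, SE 0.58), the ERK phosphatase DUSP5 (4.06, SE 0.66) and the NRF2 target OSGIN1 (3.78, SE 0.68) rose as well. MSX1 had 0 counts in HCC827 with DMSO and was at least 12.6-fold higher there. GDF15, a secreted stress cytokine, rose by 3.35 (SE 0.57), SESN2 by 3.40 (SE 0.59) and the kinase PLK3 by 3.32 (SE 0.56).

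HSPE1-MOB4, a readthrough model, and FRG2B had 0 counts in all DMSO libraries. With AL-X, HSPE1-MOB4 had 2919, 243 and 164 counts in A549, HCC827 and H1975, at least 1760-fold, 95.7-fold and 67.7-fold higher. FRG2B had 2754, 42 and 83, at least 1661-fold, 16.5-fold and 34.3-fold higher. The group means, which A549 dominates, were at least 681-fold and 610-fold higher. RFPL4A was at least 2154-fold higher in A549. These 3 share sequence with neighbours or copies, and their counts are uncertain. Among other nuclear genes, the transcription factor NFIB fell by 2.95 log2 units (SE 0.52), the metalloreductase STEAP2 by 3.67 (SE 0.65) and the spectrin SPTB by 2.81 (SE 0.49).

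In total 20 genes rose and 32 fell among 20344 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 51 of them with the same sign in 3 lines and KRT16P1 the exception. Of those that fell, 18 lie in the mitochondrial genome, 4 are nuclear copies of it and 10 are others. At unadjusted p under 0.05 there were 1114 higher and 2085 lower. No gene passed with library totals as the only scaling (2792 at unadjusted p under 0.05), with no filter (3352) or without the block by line (1722), and 4 passed when mitochondrial genes were left out (MIR22HG, HSPE1-MOB4 and FRG2B higher, ENSG00000285991 lower). DESeq2 called 608 higher and 1409 lower and limma-voom 323 and 338. Leaving out A549 gave 65 higher and 78 lower, leaving out HCC827 127 and 57, and leaving out H1975 28 and 78.

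**Figure D2:**
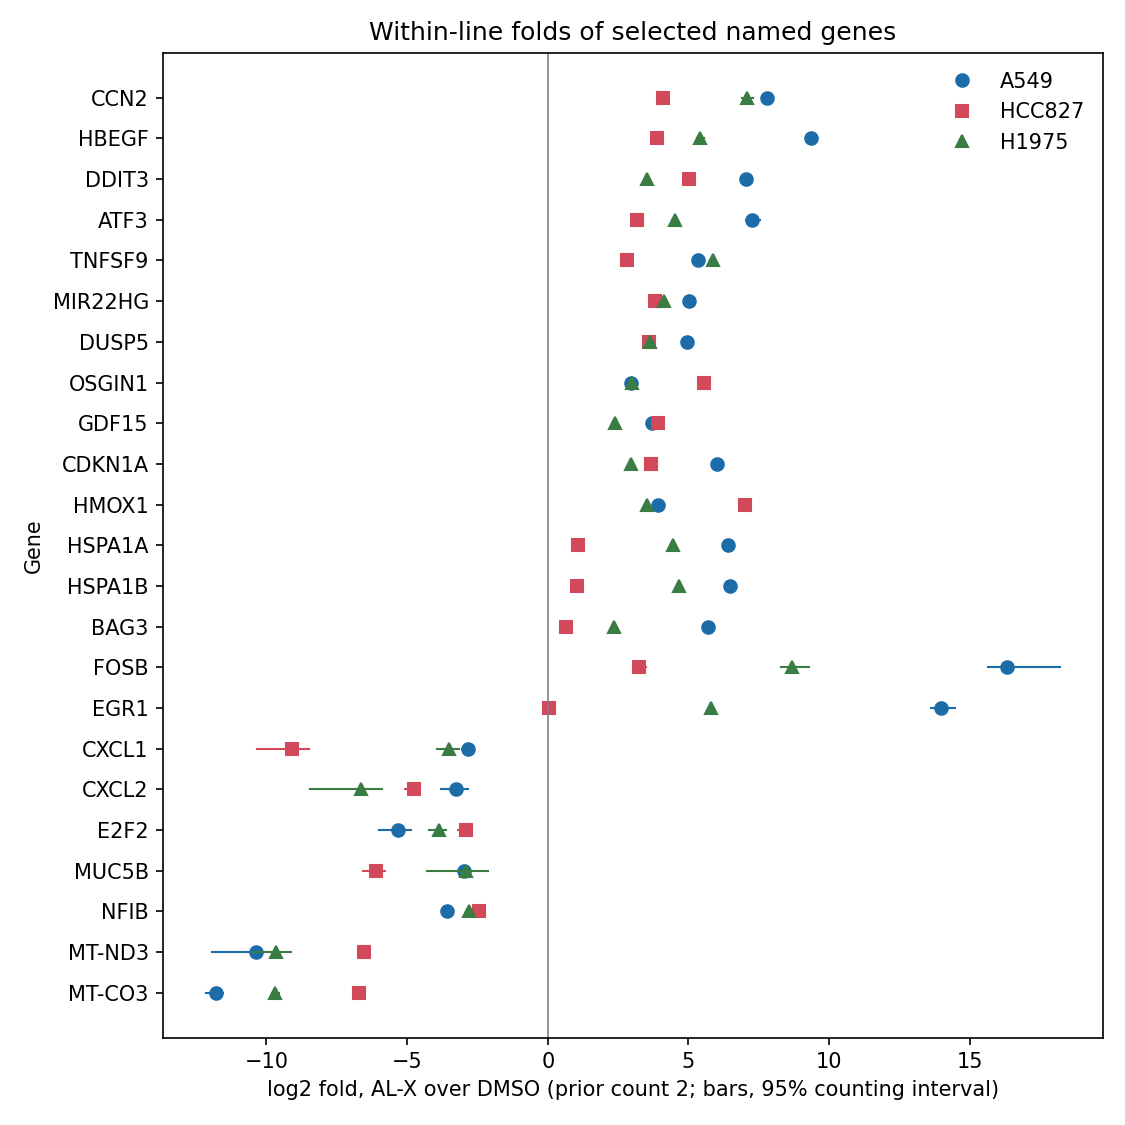
Within-line log2 fold of AL-X over DMSO (x axis, prior count of 2) for 23 genes (y axis), with points for A549, HCC827 and H1975 and bars for the exact 95% interval of the count ratio, which covers counting error only. DDIT3 and CCN2 lie to the right of 0 and MT-ND3 and MT-CO3 to the left in every line, while EGR1 ranges from 0.05 in HCC827 to 13.96 in A549.

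The within-line comparisons ask how far each line moved. In A549 3545 genes were at least 2-fold higher and 3712 lower of 11825, in HCC827 1270 and 2041 of 11898, and in H1975 1814 and 2091 of 11784. These have no replicate check. Among genes with a symbol and at least 10 CPM in the higher library, the 4 largest rises in A549 were of FOSB, ARC, EGR1 and RASD1. FOSB went from 6 to 365191 counts (log2 fold 16.31, 95% interval 15.63 to 18.19), ARC from 7 to 220376 (15.41), EGR1 from 48 to 441774 (13.96) and RASD1 from 20 to 52042 (12.05). In HCC827 the same genes were 3.24, 0.37, 0.05 and 1.60. In H1975 FOSB was 8.68 and FOS 8.01 log2 units higher, beside the small nucleolar RNA gene SNORD14E (8.55) and the readthrough model SPECC1L-ADORA2A, which was at least 479-fold higher. SNORD14E spans only 123058077 to 123058161 on chromosome 11. In size-selected poly(A) libraries its counts may not stand for the mature small RNA, which was not tested. In HCC827 the inflammasome gene NLRP2 was 7.52 higher, the heme oxygenase HMOX1 6.99, the lipase inhibitor ANGPTL4 6.09 and the readthrough model FAM47E-STBD1 6.05. The chemokines CXCL1 (-9.07), CCL20 (-8.16) and CXCL6 (-7.24) were, with MT-CO1 (-6.93), the 4 lowest there among genes with a symbol and at least 10 CPM in the higher library. MT-TL1 was 9.77 log2 units lower in H1975, from 2995 counts to 1 (95% interval -16.54 to -8.76).

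Scaling moved these counts. TMM factors in A549 were 1.12 with DMSO and 0.557 with AL-X. With library totals the median fold of the genes considered shifted by -1.0 log2 units in A549, 0.13 in HCC827 and -0.41 in H1975, so directions below are relative to that shift. The share of differing genes that were higher was then 19.5% instead of 48.8% in A549, 47.8% instead of 38.4% in HCC827 and 19.7% instead of 46.5% in H1975.

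Shared differences exceeded those of independent lists. In all 3 lines 272 genes were at least 2-fold higher, against 43.7, and 353 were lower, against 61.0. Across genes, which are not independent replicates, the folds of A549 and H1975 had Pearson r = 0.746 and Spearman rho = 0.717. Those of A549 and HCC827 had 0.369 and 0.291, and those of HCC827 and H1975 0.349 and 0.237. Genes at 2-fold in opposite directions numbered 73 for A549 with H1975, 373 for A549 with HCC827 and 209 for HCC827 with H1975.

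Of the 30 gene lists, 13 were higher and 3 lower across the lines by camera with the preset correlation. With the correlation estimated per list none passed, and the adjusted p of those 16 lay between 0.400 and 0.741. That version of camera had 2 residual degrees of freedom, and even the mitochondrial mRNAs had an unadjusted p of 0.0179 by it. Its failures therefore cannot tell an effect of correlation from too few lines. The p53, inflammatory and YAP lists failed too, though their estimated correlations (-0.025, -0.041 and -0.021) lay under the preset one. The list of the integrated stress response, driven by ATF4, rose (median log2 fold 1.35, preset adjusted p = 2.28e-12, adjusted p = 0.400 with an estimated correlation). Of its 23 members 3 rose over all genes tested (DDIT3, ATF3 and SESN2) and 10 when adjusted over the list alone. Its median was 1.66 in A549, 1.71 in HCC827 and 1.86 in H1975, at percentiles 98.4, 100 and 100 of random lists matched on expression. With library totals the medians were 0.66, 1.84 and 1.45. PPP1R15A, the stress-induced phosphatase subunit GADD34, was 5.28 (SE 1.29, adjusted p = 0.120) and TRIB3 2.01 (SE 0.56, adjusted p = 0.150). The unfolded protein response and ER chaperones were higher as a list (median 0.76, preset adjusted p = 5.03e-05, adjusted p = 0.490 with an estimated correlation), with no member of 18 past the test over all genes and 2 over the list alone. DNAJB9 was 2.92 (SE 0.55, adjusted p = 0.0567). The chaperone HSPA5 was 3.26, 1.38 and 1.99 in A549, HCC827 and H1975. The list's median in A549 was 0.92, and -0.08 with library totals.

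The NRF2 targets, antioxidant and detoxifying genes, were higher as a list (median 1.04, preset adjusted p = 6.17e-08, adjusted p = 0.434 with an estimated correlation). Of 26 members 1 rose over all genes and 3 when adjusted over the list alone. The median was 1.66 in HCC827, 1.10 in H1975 and 0.30 in A549, where it is -0.70 with library totals. Among matched random lists these lay at percentiles 100, 97.3 and 0.7. HMOX1 was 4.71 (SE 0.99, adjusted p = 0.0849), GCLM 1.77 (SE 0.68) and NQO1 1.54 (SE 0.67). The autophagy and lysosome list was higher (median 1.17, preset adjusted p = 3.45e-08, adjusted p = 0.400 with an estimated correlation), with 0 of 25 members past the test over all genes and 4 when adjusted over the list alone. MAP1LC3B was 3.24 (SE 0.73, adjusted p = 0.10).

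The heat shock list was higher (median 1.70, preset adjusted p = 3.42e-10, adjusted p = 0.592 with an estimated correlation), with 0 of 19 members past the test over all genes and 4 when adjusted over the list alone. Its median was 2.93 in A549, 1.93 in H1975 and -0.04 in HCC827, which is 0.09 with library totals, at percentiles 100, 100 and 59.8 of matched random lists. HSPA1A was 6.42, 1.07 and 4.46 in A549, HCC827 and H1975, HSPA1B 6.48, 1.02 and 4.66, and the co-chaperone BAG3 5.69, 0.64 and 2.36. HCC827 differed from the other lines on this list by camera on the interaction (preset adjusted p = 5.20e-24, adjusted p = 0.635 with an estimated correlation). Proteasome subunits (median 1.07, preset adjusted p = 9.54e-12, adjusted p = 0.624 with an estimated correlation) and cytosolic ribosomal proteins (median 0.96, preset adjusted p = 4.05e-08, adjusted p = 0.651 with an estimated correlation) were higher as lists. The estimated inter-gene correlation across lines was 0.964 for heat shock, 0.939 for proteasome and 0.990 for ribosomal genes, far above the preset value. Their members are close to 1 measurement, so the preset p-values overstate the evidence. No member of the proteasome or ribosomal list passed, over all genes or over the list alone. The ribosomal list had a median of 1.92 in A549, 1.31 in H1975 and -0.45 in HCC827, and the proteasome list 1.81, 1.17 and 0.26. Among matched random lists these lay at percentiles 85.4, 99.8 and 2.8 for the ribosomal list and 99.8, 100 and 91.8 for the proteasome list. Across protein-coding genes the fold correlated with exonic length (Spearman rho -0.347 in A549, -0.357 in H1975 and -0.0658 in HCC827). Median exonic length was 3617 bases for the ribosomal list, 4490 for the proteasome list, 3783 for the heat shock list and 3286 for nuclear respiratory chain genes. It was 3416 for NRF2 targets, 4017 for p53 targets, 4040 for the integrated stress response, 4398 for ER chaperones, 4632 for EGFR and MAPK output and 4950 for mesenchymal genes. The median for all 9664 protein-coding genes considered in 3 lines was 5399. The other higher lists lay above that, at 5655 for autophagy and lysosome, 5578 for YAP and TEAD targets and 5512 for hypoxia and glycolysis. The lists that were lower lay under it, at 784 for mitochondrial mRNAs, 2538 for inflammatory cytokines and 4046 for lung epithelial differentiation. The top members were PSMD8 (1.95, SE 0.63) and RPLP1 (1.57, SE 0.75).

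Proliferation lists did not pass across the lines. The median of DNA replication and E2F targets was -1.47 in HCC827, 0.36 in A549 and 0.41 in H1975, and with library totals -1.34, -0.65 and 0.00. That of the G2/M and mitosis list was -1.53, 0.45 and -0.05, and with library totals -1.41, -0.55 and -0.46. The preset adjusted p was 0.679 and 0.175, and 1 member of each list fell when adjusted over the list alone. In HCC827 17 of 26 E2F targets and 17 of 25 G2/M genes were at least 2-fold lower, and its difference from the other lines had a preset adjusted p of 4.20e-08 for both lists (adjusted p = 0.635 with an estimated correlation). MKI67 was -1.15 (SE 0.64), E2F2 -4.05 (SE 0.83, adjusted p = 0.0791), ASPM -2.32 (SE 0.53) and CENPF -1.81 (SE 0.57), while CCNE1 was 3.03 (SE 0.92). CCNB1 was -0.13, CCND1 -0.42 and E2F1 0.37 (SE 0.60, 0.51 and 0.47).

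The p53 targets were higher (median 0.19, preset adjusted p = 0.0136, adjusted p = 0.410 with an estimated correlation), with 2 of 25 members, GDF15 and PLK3, past the test over all genes and 3 over the list alone. CDKN1A, the cell cycle inhibitor p21, was 4.17 (SE 0.85, adjusted p = 0.0731) and MDM2 -0.68 (SE 0.55). EGFR and MAPK output genes were higher (median 0.48, preset adjusted p = 0.00444, adjusted p = 0.434 with an estimated correlation). Of 23 members HBEGF and DUSP5 rose over all genes, 5 rose and 2 fell over the list alone. The list's median was 1.16 in A549, 0.05 in HCC827 and 0.19 in H1975, at percentiles 95, 70.9 and 37.4 of matched random lists. In HCC827 9 members were at least 2-fold higher and 7 lower. With library totals the across-line median was 0.02, and that of H1975 was -0.22 instead of 0.19. DUSP6 was -2.68 (SE 0.63, adjusted p = 0.115). MYC was 1.39 (SE 0.73) and EGFR -1.41 (SE 0.80). YAP and TEAD targets (median 0.23, preset adjusted p = 0.00461, adjusted p = 0.410 with an estimated correlation) and mesenchymal genes (median 0.43, preset adjusted p = 0.00667, adjusted p = 0.627 with an estimated correlation) shared CCN2 as their only member past the test over all genes, and 4 members of each rose over the list alone. The mesenchymal median was -0.35 in A549, 0.20 in HCC827 and 0.72 in H1975, at percentiles 13.8, 91.2 and 96.7 of matched random lists, and the YAP median 0.15, 0.17 and 0.75, at 19.9, 75.7 and 91.1. CCN1 was 3.71 (SE 0.94), SNAI1 9.00, 3.72 and 4.64 in A549, HCC827 and H1975 (adjusted p = 0.0715), VIM 1.08 (SE 0.71) and CDH1 -0.87 (SE 0.91). With library totals the medians of the p53, YAP and mesenchymal lists were -0.25, -0.21 and 0.00.

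**Figure D3:**
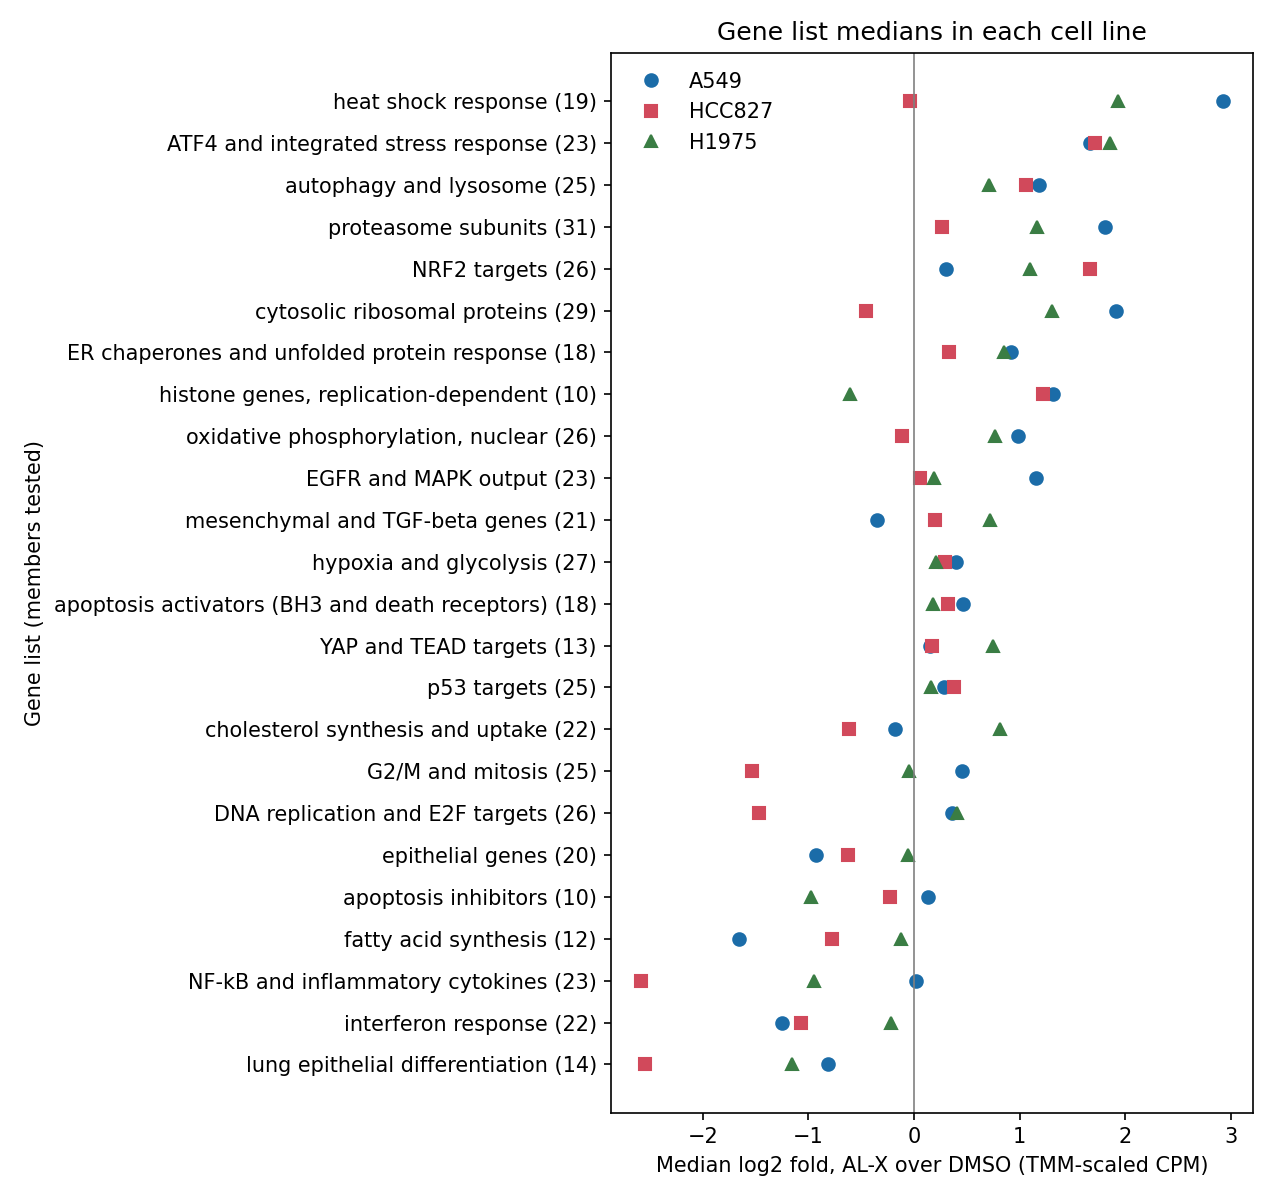
Median log2 fold of AL-X over DMSO (x axis, TMM-scaled CPM with a prior count of 2) in each line for lists with at least 10 members tested (y axis, members in brackets), without the mitochondrial mRNAs. The integrated stress response lies between 1.66 and 1.86 in all lines, while heat shock spans -0.04 in HCC827, which is 0.09 with library totals, to 2.93 in A549. The narrow range of the stress response depends on the scaling, since with library totals it is 0.66 in A549, 1.84 in HCC827 and 1.45 in H1975.

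Lists that were lower were the mitochondrial mRNAs (preset adjusted p = 2.45e-39, adjusted p = 0.400 with an estimated correlation), lung epithelial differentiation (median -2.01, preset adjusted p = 1.54e-05, adjusted p = 0.400 with an estimated correlation) and NF-kB and inflammatory cytokines (median -0.88, preset adjusted p = 0.0136, adjusted p = 0.410 with an estimated correlation). Of 14 lung genes 0 passed over all genes and 4 fell over the list alone, and the mucin MUC5B was -4.04 (SE 0.84, adjusted p = 0.0846). The lung list's median was -0.82 in A549, -2.55 in HCC827 and -1.15 in H1975, at percentiles 14.9, 0 and 0.1 of matched random lists. Only 7 members in A549 and 5 in H1975 reached 5 CPM in the higher library, against 11 in HCC827. Of these, 1 was at least 2-fold higher and 3 lower in A549, 1 and 2 in H1975, and 0 and 11 in HCC827. The medians of A549 and H1975 thus rest largely on genes of low counts. The lung list passed no more without HCC827 or without the block by line. Of 23 inflammatory genes 0 passed over all genes, and 1 rose and 5 fell over the list alone. The median was 0.02 in A549, where it is -0.77 with library totals, -2.59 in HCC827 and -0.95 in H1975. CXCL2 was -4.92 (SE 0.96, adjusted p = 0.0650) and IL11 2.64 (SE 0.53, adjusted p = 0.0715). Nuclear respiratory chain genes were higher (median 0.49, preset adjusted p = 0.00179, adjusted p = 0.741 with an estimated correlation), as were hypoxia and glycolysis genes (median 0.29, preset adjusted p = 0.0193, adjusted p = 0.627 with an estimated correlation), with no member of either past the test over all genes, and 0 and 1 when adjusted over the list alone. With library totals these 2 medians were 0.06 and -0.16, and in A549 -0.02 and -0.61. For the respiratory chain list the median was 0.99 in A549, 0.77 in H1975 and -0.12 in HCC827, at percentiles 92.1, 99.4 and 18.3 of matched random lists. This list had an estimated inter-gene correlation of 0.743, and it passed no more without A549 or without H1975. In HCC827 0 of its 26 members were at least 2-fold higher and 4 lower, and folds were lower for genes of longer exonic length in A549 and H1975. For the hypoxia list the medians of 0.40 in A549, 0.30 in HCC827 and 0.20 in H1975 lay at percentiles 10.5, 97.7 and 6.5, and in H1975 2 members were at least 2-fold higher and 5 lower. ADM, the vasodilator peptide adrenomedullin, was 3.92 (SE 1.10, adjusted p = 0.150).

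The remaining lists did not pass. Preset adjusted p was 0.354 for apoptosis activators, 0.528 for apoptosis inhibitors, 0.0574 for interferon response, 0.639 for cholesterol synthesis, 0.105 for fatty acid synthesis, 0.161 for metallothioneins, 0.0546 for AHR targets, 0.352 for epithelial genes and 0.0546 for histone genes. Markers of other cell types gave 0.639 for fibroblasts, 0.550 for leukocytes and 0.679 for endothelium. Among their members, BMF, a BH3-only activator, was -5.43 (SE 1.16, adjusted p = 0.0888), PMAIP1 2.24 (SE 0.65), BCL2L11 0.64 (SE 0.46), MCL1 2.45 (SE 1.05) and BIRC3 -3.24 (SE 0.74). IRF7 was 2.75 (SE 0.80) and MX2 -3.63 (SE 1.15), the desaturase SCD -1.92 (SE 0.80), HMGCS1 0.47 (SE 0.61) and TIPARP 3.17 (SE 0.94).

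The line-specific comparison asks whether a line responded unlike the mean of the other 2. In HCC827 53 genes differed, 18 more positive and 35 more negative. ARC (-10.50), EGR1 (-9.78), FOSB (-9.17), RASD1 (-7.80) and FOS (-7.00) were less raised there, and NLRP2 (7.32) and ANGPTL4 (5.19) more. In A549 57 genes differed, 20 more positive and 37 more negative, and IRF7 was 4.02 log2 units more positive. In H1975 edgeR called 0 genes, with 236 at unadjusted p under 0.05, 8 by DESeq2 and 2 by limma-voom. DESeq2 called 244 in HCC827 and 414 in A549 and limma-voom 148 and 44, and DESeq2 size factors in edgeR left 24 in A549.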

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

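The tests of the mitochondrial transcripts, of the weaker response of HCC827, and of gene span by line, the list tests of line differences, and the intervals over list members and genes, were chosen after the result was seen. Differences between lines were tested by an interaction term, with 1 library per line and treatment. For lists, the preset p-values of these differences take list members as units, so they do not show that a difference would repeat. With an estimated correlation, 1 residual degree of freedom was too few for a list to pass readily.

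The number of genes whose response differed from the mean of the other 2 lines was 57 in A549 and 53 in HCC827. Lists that differed with the preset correlation numbered 11 in A549, 18 in HCC827 and 9 in H1975, and 0 with an estimated one (lowest adjusted p = 0.635). In HCC827 the preset adjusted p was 5.20e-24 for heat shock, 1.76e-17 for ribosomal proteins, 1.38e-13 for mitochondrial mRNAs, 4.20e-08 for both E2F and G2/M lists, 3.53e-07 for proteasome subunits, 3.00e-05 for inflammatory cytokines and 0.000108 for NRF2 targets.

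Single genes whose effect in HCC827 lay below the other lines, in log2 units, were SPECC1L-ADORA2A (-14.66), ARC (-10.50), EGR1 (-9.78), FOSB (-9.17), HSPA6 (-8.58), SNORD14E (-8.55), RASD1 (-7.80), SOCS3 (-7.58), SGK1 (-7.05), FOS (-7.00), CXCL1 (-6.14) and CXCL8 (-5.31). Above them lay MT-TS1 (8.49), MT-TY (8.38), MT-TL1 (8.03), NLRP2 (7.32), AKR1C1 (6.21), ANGPTL4 (5.19) and SLC7A11 (4.72). In A549 FOSL1 (5.44), JUN (5.30), KLF4 (5.21) and IRF7 (4.02) lay above the other lines. The values of MT-TS1, MT-TY and SPECC1L-ADORA2A were fitted with libraries at 0 counts, depend on the prior count and are no measure of the size. The counts of SNORD14E may not stand for the mature small RNA, and those of MT-TS1 and MT-TY may include transcripts of the other strand.

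Mitochondrial mRNAs were lower in every line. Scaling is argued against, since the median across-line log2 fold of the 13 mRNAs was -8.44 with library totals. Reads moving to nuclear copies are argued against too, since mitochondrial genes and copies together were at least 10.4-fold lower in each line. A drop of respiratory chain mRNAs from both genomes is argued against by the nuclear list, whose lowest median was -0.12 (bootstrap 95% interval over members -0.42 to 0.02). A loss specific to mitochondrial transcripts, as a response to AL-X, may be the explanation, but poly(A) selection and RNA handling per library stay open and were not tested.

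Folds were lower for genes of longer span (Spearman rho -0.310 in A549, -0.121 in HCC827 and -0.283 in H1975 across genes). In A549 and H1975 they were also lower for genes of longer exonic length (-0.347 and -0.357). There rho with span was -0.130 and -0.0857 once exonic length was held. Exonic length merges all annotated exons of a gene, so it only stands in for transcript length. The 2 tests first set for all 3 lines met neither of their bounds, with a highest partial correlation of 0.0109 for exonic length given span and a highest correlation of -0.0543 within tertiles of expression. Divided by line after the values were seen, the partial correlation argues against exonic length in HCC827 (0.0109, bootstrap 95% interval over genes -0.0082 to 0.0288). The length of the transcripts present was not measured and is not excluded there. In A549 and H1975 the partial correlation was at most -0.208 (-0.226 to -0.189, on both sides of its bound of -0.2). Transcript length, through RNA breakdown or size selection, may therefore contribute in those 2 lines. Expression level is argued against in A549 and H1975 (correlation at most -0.161 in each tertile, interval -0.193 to -0.129) and in HCC827 cannot be told apart, since its tertiles lie on both sides of the bound of -0.1. A response to AL-X that depends on gene length stays open in each line.

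Heat shock genes were not raised as a list in HCC827, and a line-specific response, a lower effective dose or another time course may remain, from 1 library per treatment. A high baseline is argued against, since the HCC827 DMSO median exceeded another DMSO library by at most 0.0725 log2 CPM, with bootstrap 95% intervals over members of -0.41 to 0.29 against A549 and -0.61 to 0.63 against H1975, which pass the bound of 0.5 set beforehand for H1975 but stay under the excess of 1 over both lines that it needs, a reading chosen after the intervals were seen. Scaling is argued against by a gap of at least 1.43 log2 units under the other scalings (interval 1.01 to 2.15). A weaker response of HCC827 in general cannot be told apart, since the NRF2 list was 0.560 log2 units higher there than in the next line with an interval of -0.05 to 1.42, while HCC827 had the fewest genes at 2-fold and the least lowered mitochondrial mRNAs. Against it go the E2F, G2/M, inflammatory and lung medians, further from 0 in HCC827 (-1.47, -1.53, -2.59 and -2.55) than in both other lines, but for each the interval of that excess reaches 0 under at least 1 scaling. The integrated stress response median was 1.71 in HCC827, against 1.66 in A549 and 1.86 in H1975. With library totals it was 1.84, 0.66 and 1.45. Its HCC827 excess had an interval of -1.58 to 0.81 with TMM and does not decide.

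For the across-line calls, 10 splits of the 6 libraries are too few to give a share under 0.05. The real split called 52 genes, the highest other 0, and 1 of the 10 reached the real count. Of the other splits, 3 part all pairs as the real one does, and 6 part 1 pair.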

How the results depend on the processing

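Leaving mitochondrial genes out, and the list tests of line differences, were chosen after seeing the data, and the cause of changes was not tested unless given. Genes higher and lower across lines numbered 20 and 32, and 52 of 52 calls were kept with DESeq2 size factors. They were 0 and 0 with library totals (2792 at unadjusted p under 0.05), 0 and 0 with no filter (3352), 0 and 0 without the replicate block by line (1722), 608 and 1409 with DESeq2, 323 and 338 with limma-voom, and 3 and 1 with mitochondrial genes left out. Leaving out 1 line gave 28 to 127 higher and 57 to 78 lower, and 46, 45 and 32 of the 52 calls were kept without A549, HCC827 and H1975. Of 100 named genes, DESeq2 size factors changed no call, and HBEGF and OSGIN1 passed no more with the 1 CPM filter.

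Within lines, library totals gave 1471 higher and 6075 lower in A549, 829 and 3378 in H1975, and 533 lower in all 3 lines. A floor of 1 CPM gave 3428 lower in H1975 and 628 lower in all 3. At 1.5-fold there were 2645 higher and 3335 lower in HCC827, 3459 and 3223 in H1975, and 753 and 813 in all 3, since the threshold is looser. Line-specific calls were 24 in A549 with DESeq2 size factors, 414 in A549, 244 in HCC827 and 8 in H1975 with DESeq2, and 148 and 2 in HCC827 and H1975 with limma-voom.

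Of the gene lists 16 passed, 0 with an estimated correlation, and likewise 0, 0 and 0 for the 3 line contrasts. Without the block 3 of the 16 passed no more (inflammatory, mesenchymal and lung lists), and the epithelial list turned up (adjusted p = 0.808). Without A549 the respiratory chain list passed no more, and G2/M (down) and AHR lists passed. Without HCC827 the p53, inflammatory and lung lists passed no more, and cholesterol (up), metallothionein and AHR lists passed. Without H1975 the respiratory chain and mesenchymal lists passed no more, and interferon and histone lists passed. With 1 line left out, the adjusted p of lists that turned at least once ranged from 0.0683 to 0.253 for E2F targets, 8.91e-05 to 0.361 for G2/M, 0.272 to 0.953 for epithelial genes, 0.0450 to 0.246 for cholesterol synthesis and 0.280 to 0.770 for endothelium.

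Genes uncalled in the main test changed sign, and 1 of them, SOCS3, passed when HCC827 was left out. With library totals E2F1 was -0.066 and SLC7A11 -0.14. With limma-voom SPECC1L-ADORA2A was 0.80 and AKR1C1 0.29. Without the block SPECC1L-ADORA2A was 2.01, CCNB1 0.15, CDH1 0.015 and SLC7A11 -0.14. With 1 line left out the ranges were -4.76 to 3.85 for SPECC1L-ADORA2A, -0.58 to 0.50 for CCNB1, -1.90 to 0.34 for CDH1, -1.24 to 1.89 for SLC7A11, -1.62 to 1.63 for AKR1C1, -0.0097 to 4.30 for SOCS3, -2.33 to 0.75 for CXCL8 and -0.12 to 1.04 for HMGCS1. Depth does not limit abundant genes at totals of 98139178 to 126840915 counts, but 3 counts are worth up to 0.0445 CPM.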

Other observations

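The test of mitochondrial position and the intervals over members were chosen after the result was seen. Genes chosen after their values were seen describe HCC827 and A549 further. The inducible chaperone HSPA6 was 11.69 log2 units higher in A549, 7.42 in H1975 and 0.92 in HCC827. The cystine transporter SLC7A11 was 3.52 higher in HCC827, -2.56 in A549 and 0.16 in H1975, and the reductase AKR1C1 was 4.61, -1.35 and -1.78. SOCS3, a feedback inhibitor of cytokine signalling, was 5.58 in A549, 3.10 in H1975 and -3.23 in HCC827, the kinase SGK1 7.29, 5.44 and -0.68, and the chemokine CXCL8 1.83, -0.24 and -4.51. Among transcription factors, KLF4 was 6.78 in A549, 1.23 in HCC827 and 1.91 in H1975, JUN 5.27, 0.97 and -1.03, and FOSL1 6.63, 1.47 and 0.90.

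The median of NRF2 targets was lowest in A549, a line known to carry mutant KEAP1, at percentile 0.7 of random lists matched on expression. A high baseline was tested as a hypothesis. The median of the list in the DMSO libraries was 9.62 log2 CPM in A549, 5.82 in HCC827 and 5.99 in H1975, an excess of at least 3.62, and 26 of 26 and 25 of 26 members were higher in A549 than in HCC827 and H1975. A high starting level may therefore go with the low median in A549, from 1 DMSO library per line.

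Several readthrough models were among the genes with the largest folds. A general rise of readthrough transcription was tested over 74 annotated models against the mean fold of their 2 genes. The median difference was 0.12 in A549 (bootstrap 95% interval -0.58 to 0.72), 0.31 in HCC827 (0.01 to 0.67) and -0.09 in H1975 (-0.65 to 0.31). The quartiles were -1.21 and 1.69, -0.92 and 1.44, and -1.18 and 0.62. With a middle value of 0.116 and members on both sides of 0, the test does not decide.

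A loss of mitochondrial mRNAs that grows with distance from the heavy-strand promoter was tested over 12 mRNAs. Spearman rho of position and fold was 0.063, 0.014 and 0.231 in A549, HCC827 and H1975, with bootstrap 95% intervals of -0.62 to 0.69, -0.65 to 0.80 and -0.39 to 0.82. The highest value of 0.231 does not decide at this number of genes. The ribosomal RNAs, nearer the promoter, had medians of -4.58, -0.79 and -3.51, less lowered than the mRNAs, but are 2 genes of another RNA class. The tRNA gene beside them, MT-TL1, was -10.14 in A549 and -9.77 in H1975, and the nearest mRNA, MT-ND1, was -9.65 and -8.29 there, against -8.67 and -6.82 for the distant MT-ND5. In HCC827 MT-TL1 was -2.66, MT-ND1 -4.33, the least lowered mRNA, and MT-ND5 -4.41.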
